A study of Bos indicus with 72 samples.

How the data were processed

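RNA was extracted with a phenol reagent and a column kit and sequenced as paired ends after library preparation with a TruSeq kit, per the labels' protocols. The deposited files fell into 3 kinds. For hypothalamus, pituitary and both ovaries the authors deposited raw counts of reads per gene, 1 file per library, with rows for reads in no gene, in more than 1 gene and aligned to more than 1 place. Those rows name no gene and stayed out of library sizes and tests. Reads in no gene made up a median of 58.6% in the hypothalamus, 56.4% in the pituitary, 89.7% in the left ovary and 89.8% in the right ovary. For the liver the deposited values were RPKM, reads scaled to gene length and library size, per the values themselves. For the uterus the deposited values were on a log2 scale and never below 0. The genome build is UMD3.1, per the submitters' processing notes. The aligner, the counting tool, its use of strand and the annotation are not given in the sources used here.

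Whole reads were recovered from the liver RPKM values by searching for the library total and the gene length that make every value of a gene a whole number of reads, within 0.003 reads. This held for 17852 of the 17853 genes with a value above 0, and for none of 300 genes when the library totals were shifted by 1 library, where 277 of the same genes came out whole with the true totals. The uterus values behaved as the absolute value of log2(RPKM + 0.001): 3132 of 173244 values lay at 9.97, the size of log2 of 0.001, and 24423 values, 14.1% of all, were recovered as below 0. The sign was taken from the reading that gave whole reads. It was left open for 1226 values, 0.708% of all, and 2510 genes held both signs. Of the values read as below 0 with under 200 reads, 100.0% were whole with the true library totals and 0.836% with shifted ones. The 100.0% follows from the rule, since whole reads decided these signs, so it is no separate check of them. For 102 uterus genes no length tried gave whole reads. On simulated data 99.7% of signs came back correctly.

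Groups were taken from the labelled status and animal number, never from values. Each animal was an independent replicate. The main test for counts was edgeR 4.0.16 with the quasi-likelihood F test, TMM factors, the filterByExpr filter and robust dispersions, per tissue. The plan made before the data were examined used edgeR for liver and uterus too. Because these files hold RPKM and log2 values, limma 3.58.1 was run instead on log2(RPKM + 0.5), with an intensity trend and robust variances, on genes at 0.5 RPKM or more in at least 5 libraries. That filter and pseudocount were chosen once the unit was known. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors of edgeR changes were taken from the F statistic. The 2 ovaries of an animal were compared with the animal as a block. The pairing comes from the labelled animal number: over 2732 genes the deviations of the 2 ovaries from their group means correlated with a median r of 0.229 within an animal, above 0.1 in 11 of 12 animals, against a median of -0.0244 between animals. The lowest r within an animal was -0.0267. In 7 of 12 animals the left ovary correlated best with the right ovary of the same animal, so the pairing was not settled for every animal.

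Genes to be named were to be those with the largest rises and falls among genes past the threshold, with a mean of at least 5 CPM (RPKM in the uterus) in the higher group, a gene symbol and no overlap between groups. The identifiers in the files match no row of the RefSeq table at hand (0 of 34142 genes), so the condition on symbols could not be met. Only the first rise and the first fall in the right ovary and in the uterus are given by identifier. For the same reason 44 gene lists fixed beforehand, from reproductive hormone networks to cell type markers, could not be tested, and no coordinates are given. Genes that overlap, lie antisense to each other or have near-identical copies may share reads in these counts.

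No pair of libraries of a group was a duplicate: the mean chi-square per gene between libraries of a group was at least 3.72, where sampling noise gives 1. File names split each tissue into 2 library sets of 6 libraries with both groups in each, and a term for the set was an alternative. Others were DESeq2 1.42.0, RLE factors, no filter on low values, limma voom with sample quality weights, leaving out each animal in turn, leaving out animals 2054 and 2059, and reading them as labelled or as in the other tissues. Pseudocounts of 0.1, 1 and 0.001, edgeR, DESeq2 and voom on recovered reads, uterus values without recovered signs, leaving out animals 2047 and 2059, leaving out the most abundant ovary gene or the genes holding 50% of a side's gene reads and thinning the ovaries to equal depth were added after seeing the data. The main fits, and DESeq2 and voom for the tissues with counts, were tested on simulated data with 200 changed genes. Fits with RLE factors, without a filter or on recovered reads, and DESeq2 on the ovary sides, were not. In simulated right ovary data edgeR recovered 96.5% of 4-fold changes, 48.3% of 2-fold changes and 7.94% of 1.5-fold changes, and in simulated uterus data limma recovered 75.8%, 37.3% and 2.99%. Simulated counts were filtered again, and edgeR and voom were scored only on genes that passed. In the right ovary these were 57 of 66 4-fold genes, 60 of 67 2-fold genes and 63 of 67 1.5-fold genes. R 4.3.3 and Python 3.11.15 were used.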

Results

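RNA was sequenced from 6 tissues of 12 Brahman heifers, a Bos indicus beef breed, to ask how gene expression differs around puberty. The tissues were hypothalamus, pituitary, liver, left ovary, right ovary and uterus, with 1 library per animal and tissue and 72 libraries in all. By its labels each tissue had 6 pre-pubertal and 6 post-pubertal libraries. The labels of 2 animals, 2054 and 2059, disagreed between tissues. Animal 2054 was labelled pre-pubertal in 4 tissues and post-pubertal in liver and uterus, and animal 2059 the other way round. Liver and uterus libraries with those numbers were therefore left out of the comparisons, which rest on 5 libraries against 5. Whether a number names the right animal is a separate matter. In genes that mark single animals, the liver libraries that matched animals 2054 and 2059 best were those numbered 2048 and 2064. Both were kept. Their r was 0.438, the lowest best match in the liver, and 0.748.

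The number of reads in genes differed widely between tissues. It lay between 4.84 and 10.4 mega-reads (M) in the hypothalamus and between 4.43 and 9.76 M in the pituitary. The ovaries held far fewer, from 185848 to 272306 in the left and from 184808 to 334454 in the right. Between 0.352% and 0.681% of left ovary reads and between 0.603% and 1.10% of right ovary reads fell in genes, against a median of 35.0% in the hypothalamus and 35.5% in the pituitary. In the ovaries the median share of reads in no annotated gene was 89.7% on the left and 89.8% on the right. Ovary results therefore describe only genes with enough of these counted reads. Whether the counted reads are an even sample of the ovary gene reads was not settled, so these genes need not be the most abundant in the ovary. Gene reads recovered from the liver values lay between 18.5 and 25.5 M, and those from the uterus values between 17.1 and 23.7 M.

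**Figure D1:**
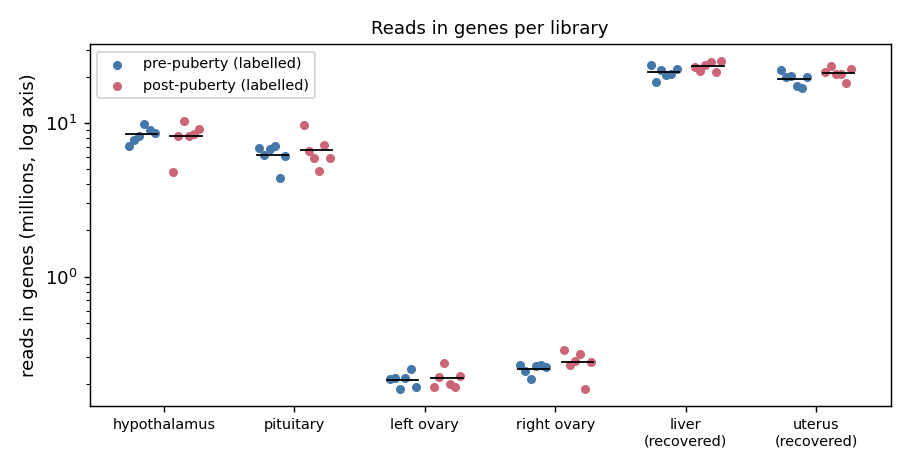
Reads in genes per library, in M on a log axis, for each tissue, with libraries labelled pre-puberty in blue and post-puberty in red and the group mean as a line; liver and uterus totals were recovered from normalized values. The ovary libraries hold 0.185 to 0.334 M, and those of the other tissues 4.43 to 25.5 M.

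The largest number of genes past the threshold was in the uterus. Of 13024 genes tested, 508 changed between the 5 pre-pubertal and 5 post-pubertal heifers, 279 upward and 229 downward (limma, Benjamini-Hochberg adjusted p under 0.05). The median change was 1.35 on the log2 scale among the genes that rose and -1.20 among those that fell. A rise of 4-fold or more was seen in 63 genes and a fall of that size in 42. Many of the rising genes were already well expressed: their median level went from 8.21 RPKM before puberty to 25.3 RPKM after it, and 31 of them had a mean under 1 RPKM before puberty. The genes that fell went from a median of 9.78 RPKM to 2.95 RPKM. The 5 post-pubertal and 5 pre-pubertal libraries did not overlap for 246 of the genes that rose and 196 of those that fell, and lack of overlap was seen in 7.29% of all genes tested where random grouping gives 0.794%.

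The files do not pair their gene identifiers with gene names, so functions cannot be given. The largest rise among separated genes was that of ENSBTAG00000001388, from 7.98 ± 2.61 RPKM (SD, n = 5) before puberty to 787 ± 837 RPKM (SD, n = 5) after it, a change of 5.56 ± 0.86 (SE) on the log2(RPKM + 0.5) scale with a limma adjusted p of 0.0072. The spread among post-pubertal heifers was wide, from 41.0 to 1924 RPKM, but all 5 lay above the highest pre-pubertal value of 10.3 RPKM. The largest fall was that of ENSBTAG00000037693, from 32.8 ± 14.0 RPKM (SD, n = 5) to 0.943 ± 1.48 RPKM (SD, n = 5), a change of -4.90 ± 0.56 (SE) with a limma adjusted p of 0.0013. Of its 5 post-pubertal values, 3 lay below 1 RPKM and rest on a recovered sign, and on the values as deposited the fall was -2.04 with a limma adjusted p of 0.245. Over its 23 alternatives the adjusted p lay between 6.84e-05 and 0.737. Folds on this scale understate the change of genes at low levels.

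Within the first library set of the uterus, the 6 libraries of the main comparison gave 14 called genes, and within the second, the remaining 4 libraries gave 47. All 508 genes kept their direction in each set, a check on genes chosen from both sets together. With the animals in doubt added as labelled for the uterus, 1598 genes were called, and with their status in the other 4 tissues limma called 0, with 880 at an unadjusted p under 0.05, and no other tool was run on that reading. On reads recovered from the same 10 libraries, tests added after seeing the data, DESeq2 called 1598 genes, 889 upward and 709 downward, and voom with quality weights 1390, 757 upward and 633 downward. The count was 215, 178 and 166 without pre-pubertal animals 2046, 2055 and 2060 in turn, and 306 and 323 without post-pubertal animals 2057 and 2061.

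In the right ovary 50 of 2073 genes changed with puberty, 44 upward and 6 downward (edgeR quasi-likelihood test, 6 animals against 6). DESeq2 called 165, 132 upward and 33 downward, edgeR without a filter on low counts 265, 182 upward and 83 downward, and voom with quality weights 26, 23 upward and 3 downward. The 44 rising genes had a median change of 1.86 on the log2 scale, and 40 of them rose at least 2-fold. The median fall was -1.04. Overlap was judged on CPM, counts scaled to library size, without TMM factors. Such values also depend on the share of reads that the most abundant gene takes. The groups did not overlap for 11 of the genes that rose and 3 of those that fell. Lack of overlap was seen in 3.96% of all genes tested, where random grouping gives 0.216%. Of these, ENSBTAG00000021588 rose the most, from 8.15 ± 6.91 counts scaled to library size (CPM; SD, n = 6) before puberty to 104 ± 48.2 CPM (SD, n = 6) after it, with a log2 change of 4.41 ± 0.65 (SE) and an edgeR adjusted p of 0.0016; CPM are of all gene reads, and the change is after TMM scaling. Before puberty the values of ENSBTAG00000021588 lay between 0 and 20.5 CPM in libraries of 216153 to 266077 gene reads. That level thus rests on few reads per library, and the size of the rise is uncertain. ENSBTAG00000047551 fell the most, from 278 ± 118 CPM to 74.3 ± 46.3 CPM (SD, n = 6 each). Its log2 change was -1.55 ± 0.36 (SE), with an edgeR adjusted p of 0.032. The call for this gene was lost without any 1 of the animals 2046, 2054, 2057, 2059 and 2060, without 2059 and either 2047 or 2054 together and with voom, although it stayed lower after puberty, with log2 changes between -1.76 and -1.30 over 22 alternatives.

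**Figure D2:**
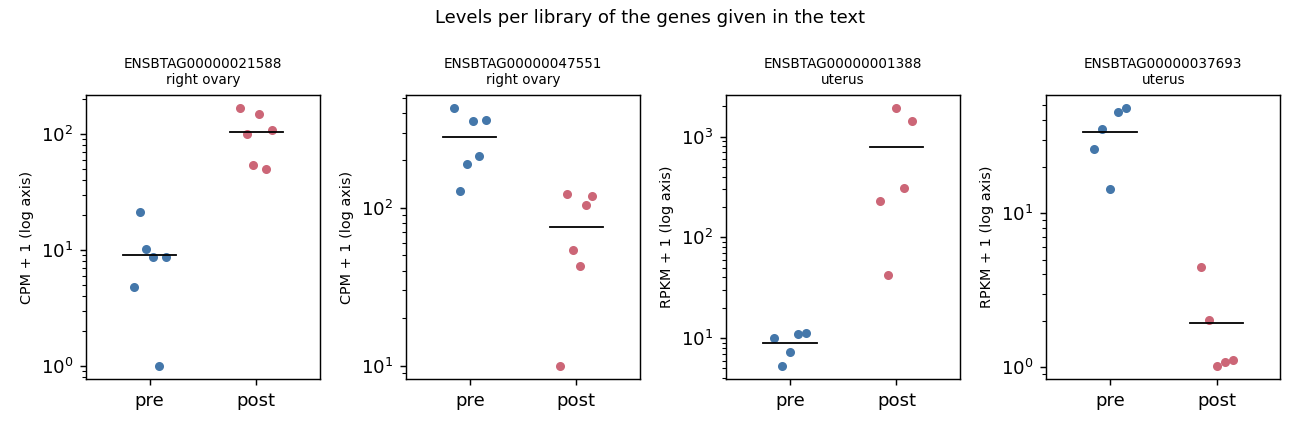
Levels per library of the largest separated rise and fall in the right ovary (CPM + 1) and in the uterus (RPKM + 1), on log axes, with pre-pubertal libraries in blue, post-pubertal in red and the group mean as a line. The post-pubertal right ovary libraries of ENSBTAG00000021588 average 104 CPM, against 8.15 CPM before puberty.

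The most abundant gene took a median of 19.2% of the gene reads in the 6 post-pubertal right ovaries and of 11.9% in the 6 pre-pubertal ones, with the highest shares, 33.1% and 28.1%, in animals 2047 and 2059. The library of 2047 also had the largest share of reads in genes, 1.10%, and the fewest genes with reads, 7494. The right ovary count was 21 without post-pubertal animal 2059, 29 without 2047 and 88 without 2061, and 33 without pre-pubertal animal 2054. Without animals 2047 and 2059 together it was 21, 18 of them among the original 50, and without 2054 and 2059 together it was 19. The first library set of 6 libraries gave 16 called genes on its own, and the second 0, with 254 at an unadjusted p under 0.05. The 50 genes moved the same way in the first set, as did the 47 of them measured in the second, though they were chosen from both sets together.

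In the left ovary none of 1922 genes passed edgeR's threshold, and 102 had an unadjusted p under 0.05 where chance gives 96.1. DESeq2 and limma voom with quality weights also called 0, and edgeR without a filter on low counts called 4. The sides were then compared directly, with the animal as a block. Library sets were defined within each side and had no term in this comparison. Between right and left, none of 1922 genes passed edgeR's threshold, although 304 had an unadjusted p under 0.05 (15.8%, where chance gives 5%); DESeq2 called 24 and edgeR without the filter 82. For the difference of the puberty change between sides, none passed with edgeR, 112 had an unadjusted p under 0.05, DESeq2 called none and edgeR without the filter called 6. Whether the puberty change differed between sides thus depended on the filter.

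Counts of the left and right ovary were summed per animal, because the corpus luteum, the gland that forms after ovulation, sits in 1 ovary and the labels do not say which. Of 3212 genes, 10 changed in the summed ovary, 9 upward and 1 downward, with a median rise of 1.80 and a fall of -1.18 on the log2 scale (edgeR, 6 animals against 6). DESeq2 called 119, 103 upward and 16 downward, edgeR without a filter on low counts 208, 161 upward and 47 downward, and voom with quality weights 2. ENSBTAG00000021588 led again, from 6.48 ± 4.33 CPM (SD, n = 6) to 66.8 ± 27.9 CPM (SD, n = 6). Before puberty its summed values lay between 3.87 and 15.1 CPM, again few reads per animal. Of the 9 genes that rose, 6 were tested in the right ovary, which contributes to the sum, and all 6 rose there. The count was 4 without animal 2047, 19 without 2049, 17 without 2054, 59 without 2056 and 77 without 2061. Without 2054 and 2059 together it was 7, of which 3 rose and 4 fell and 3 were among the original 10, and without 2047 and 2059 together it was 1. Within the library sets it was 5 and 17.

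No gene passed the threshold in the hypothalamus, the pituitary or the liver. In the hypothalamus, edgeR tested 13713 genes and found 475 with an unadjusted p under 0.05, where chance gives 686; DESeq2 called 1 and voom 0. In the pituitary, edgeR tested 13335 genes and found 203 with an unadjusted p under 0.05, where chance gives 667; DESeq2 and voom called 0. In the liver, limma tested 11697 genes in 5 libraries against 5 and found 200 with an unadjusted p under 0.05, where chance gives 585. On the reads recovered from the liver values, edgeR and voom called 0 and DESeq2 called 1. In genes that mark single animals, all 12 liver libraries matched another animal than their number, of the same status in the 10 compared. In simulated data a 4-fold change was recovered in 93.7% of changed genes for the hypothalamus, 95.5% for the pituitary and 89.4% for the liver. A 2-fold change was recovered in 68.2%, 73.4% and 58.2% and a 1.5-fold change in 34.8%, 28.4% and 23.9%, so small changes were mostly not detectable. The simulated genes varied independently of each other, which real genes need not do. These shares may therefore not hold for the real libraries, and larger changes are not ruled out.

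**Figure D3:**
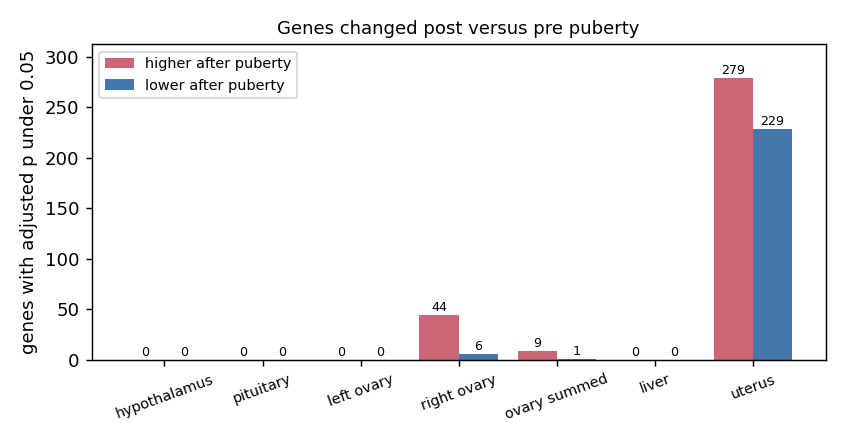
Number of genes with an adjusted p under 0.05 that were higher (red) or lower (blue) after puberty, per tissue and for the summed ovary, on an axis that starts at 0. The uterus had 279 and 229, the right ovary 44 and 6, the summed ovary 9 and 1, and the other tissues 0.

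Few genes changed in both the uterus and the right ovary. Among 1824 genes tested in both the uterus and the right ovary, 2 rose in both, against 0.85 for independent lists of those sizes, and none fell in both. In the opposite sense, 3 genes rose in the right ovary and fell in the uterus, against 0.488. The same heifers gave every tissue, so the lists are not independent, and no test was made of these overlaps.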

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

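The tests of animal labels, of ovary sequencing depth and of the genes holding 50% of the right ovary reads were chosen after the result was seen. The test of the difference between sides was planned, but how to read it was set after its result was seen, and the ovary profile test, set as a whole beforehand, was divided into left and right after its values were seen. In 48 groups tested for a value far from the rest, 6 stood out, where chance gives 2.4. Among pre-pubertal hypothalamus libraries, that of animal 2054 had 30.7% of reads in genes, with the nearest other at 34.0%, and 15.1% of reads not aligned uniquely, with the nearest other at 7.15%. Among pre-pubertal left ovary libraries, that of 2060 had 0.352% of reads in genes, against 0.592% for the nearest, and 50.3% not aligned uniquely, against 10.3%. Among pre-pubertal right ovary libraries, that of 2046 had 16.7% not aligned uniquely, against 10.7%. Among post-pubertal pituitary libraries, the most abundant gene took 35.2% of the gene reads in that of 2057, against 16.3% in the nearest.

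Very few ovary reads were counted in genes, with a median of 89.7% of left and 89.8% of right ovary reads in no annotated gene. Shallower sequencing is argued against: an ovary library held a median of 36.6 M (mega-reads), counted in genes or not, above the lowest hypothalamus library at 13.8 M. If the counted reads were an even sample of the gene reads, the ovary profile would resemble the uterus at least as closely as the least similar pair of other tissues, hypothalamus and liver, with a Spearman's rho of 0.551 across genes at equal depth (genes are not independent replicates). The left ovary gave 0.526, below that bound beyond the range of 20 thinnings, and the right ovary gave 0.561, above it. Why the ovary reads fell outside genes stays open, and no biological explanation was tested.

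The conflicting labels of animals 2054 and 2059 were examined with 67 genes selected because their level marks single animals in both hypothalamus and pituitary. The thresholds were r above 0.8 and SD above 0.35, of 3 pairs of thresholds tried. Of the 67 genes, 56 were used in the uterus and 63 in the liver, those with values and an SD above 0.2 there. The other 2 pairs of thresholds selected 13 and 158 genes and gave the same counts of matches in uterus and liver. In the uterus 10 of 12 libraries matched their own animal best and the other 2 matched each other's (2 of 2, with r of 0.727 and 0.643), while on the 508 genes called without them both lay on the side of their own label (2 of 2), at 0.982 and -0.105 where the pre-pubertal mean is 0 and the post-pubertal mean is 1, so exchanged animal numbers may explain the conflict there and wrong status labels are argued against. For these 2 libraries the animal of their own number came second, with r of 0.509 and 0.410. Those were the highest second values in the uterus, so the exchange is less clear than the best matches alone show. In the liver 12 of 12 libraries matched another animal, in reciprocal pairs, of the labelled status in the 10 libraries compared. The other 2 went against their labels: that numbered 2054, labelled post, matched pre-pubertal animal 2048, and that numbered 2059, labelled pre, matched post-pubertal animal 2064, and the headers of the liver files likewise give 2054 as pre and 2059 as post. In every liver pair the 2 libraries carried the same letter in the headers of the 2 library sets. Animal numbers exchanged between the sets may therefore explain the liver matches. The liver matches to the animals in doubt were the least clear. The library numbered 2048 matched animal 2054 with r of 0.438, the lowest best match in the liver, and its second r was 0.166. The library numbered 2064 matched animal 2059 with r of 0.748, but its second r was 0.638, the highest second value in the liver. In the ovaries 6 of 12 left and 8 of 12 right libraries matched their own animal best. The median r with the best animal was only 0.235 and 0.301 there, so these genes did not settle the ovary numbers. No library was moved between groups, and no biological explanation was tested.

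More genes were called in the right ovary than in the left. The most abundant genes do not account for it, since 49 genes were called in the right ovary without the most abundant one. Without the 40 that hold 50% of its gene reads 37 were called, and 5 of the original 50 calls were among those 40. Depth does not account for it either, since 37 were called with all ovary libraries thinned to the lowest total. Nor do library sets within a side, since 54 were called with a term for the set and none in the left ovary. The sets were defined within each side, so that term cannot test a difference between the left and right libraries themselves. The difference between sides called 0 genes with edgeR and with DESeq2 (112 at an unadjusted p under 0.05 with edgeR) and 6 with edgeR without a filter on low counts, so whether puberty acts more on the right ovary cannot be told apart from chance variation in low counts.

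Chance was examined by drawing 100 splits of the animals for each test, the real one included, or for right against left 100 exchanges of sides within animals. In the uterus 1 of 100 splits gave as many genes as the real 508, with 2 as the highest other, in the right ovary 1 of 100 gave as many as the real 50, with 4 as the highest other, and in the summed ovary 1 of 100 gave as many as the real 10, with 2 as the highest other. Chance is excluded for those at this level. Where the real count was 0, all 100 splits gave as many by construction. The highest other split called 155 genes in the hypothalamus, which points to a structure of those libraries that was not identified, 5 in the left ovary, 1 in the pituitary, 1 in the liver, 23 for right against left and 1 for the difference between sides.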

How the results depend on the processing

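Tests on recovered reads, other pseudocounts, uterus values without signs, ovaries without their most abundant genes, thinned ovaries and ovaries without animals 2047 and 2059 were added after seeing the data, and the count tools planned for liver and uterus could be run only on recovered reads. No alternative that gave a value for a gene named in the text reversed it. ENSBTAG00000001388 has no value on recovered reads, because its highest deposited values carry too few decimals to give whole reads, and ENSBTAG00000021588 was not tested in the thinned right ovary. In the hypothalamus DESeq2 called 1 gene, in the liver DESeq2 on recovered reads called 1, and in the left ovary edgeR without a filter called 4; the pituitary stayed at 0 in all 18 alternatives. In the right ovary DESeq2 called 165, edgeR without a filter 265, and voom with quality weights 26; 19 were called without animals 2054 and 2059, of which 17 were among the original 50, and 21 without 2047 and 2059. Leaving out each animal gave 21 to 88. In the summed ovary DESeq2 called 119, edgeR without a filter 208 and voom with quality weights 2, 1 was called without 2047 and 2059, and leaving out each animal gave 4 to 77. In the uterus the count was 1598 with animals 2054 and 2059 as labelled, 0 with their status in the other tissues, 1598 with DESeq2 and 1390 with voom on recovered reads, and leaving out each animal gave 166 to 731. Between ovary sides DESeq2 called 24 and edgeR without a filter 82, and for the difference of the puberty change between sides edgeR without a filter called 6. Without the replicate block, 0 genes were called in either ovary side test, as with it. The causes of these differences were not tested, except that fewer animals or more tested genes are part of some alternatives. In simulated data 5.93% of DESeq2 calls were false against 2.20% for edgeR in the right ovary, and 15.6% against 4.51% in the hypothalamus. DESeq2 was fitted and scored there on the 2073 and 13713 genes past edgeR's filter, and edgeR was scored on the 1870 and 13586 that passed again. On the real counts DESeq2 had no such filter and tested 15973 and 19227 genes. The simulated shares of false calls need not hold for those runs. The largest ovary library held 0.334 M gene reads, and depth there limits the tests to 1922 genes on the left and 2073 on the right.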

Other observations

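Gene groups were defined after seeing the data by the tissue in which a gene was at 5 RPKM or more and at least 10 times the highest of the 3 other deeply counted tissues. Of 106 genes highest in the uterus, 104 were tested there. Of these, 18 rose and 6 fell after puberty, and 68 lay higher, with a median log2 change of 0.39 against -0.03 for all genes (camera adjusted p = 0.000159 over 40 tests). With an estimated correlation that call was lost, with an adjusted p = 0.408. Genes entered this group by their level in the uterus, the tissue tested here. The test was thus not independent of the selection, and no conclusion on puberty is drawn from it. In the uterus, of the genes highest in the hypothalamus 4 rose and 5 fell, and of those highest in the liver 3 rose and 6 fell; neither group passed the camera test there.

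In the pituitary 57 genes of the uterus group were tested, and edgeR called 0 of them. Of these 44 lay lower after puberty, with a median log2 change of -0.20 (camera adjusted p = 3.63e-06), and with an estimated correlation the call was lost, with an adjusted p = 0.084. Of the genes that fell in the uterus, 124 of 190 tested lay lower in the pituitary, with a median of -0.07 (camera adjusted p = 0.00778, and adjusted p = 0.227 with an estimated correlation). Pituitary and uterus come from the same heifers. Genes that rose in the uterus passed no camera test in any other tissue.

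A term between the 2 library sets called 127 genes in the left ovary and 0 in the right ovary, the hypothalamus, the pituitary, the liver and the uterus. Of the reads in the 14384 genes with counts or recovered reads for all 6 tissues, summed over libraries, the most abundant ovary gene took 13.9% in the left ovary and 19.3% in the right, against 0.399% in the hypothalamus and 0.00397% in the uterus.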
